A study of Mus musculus with 42 samples.

How the data were processed

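RNA was measured by poly(A) RNA sequencing in 42 mouse libraries, 22 of homogenised distal colon and 20 of intestinal epithelial cells lysed directly. The tables deposited by the authors hold raw counts per Ensembl gene, as shown by whole numbers in every column, with 55414 genes in each table. Per the labels, the submitters used Trimmomatic 0.39 and STAR 2.7.8a against genome build GRCm39, and R 4.4 with DESeq2. The counting step, its strand setting, the treatment of reads that fit several genes and the annotation release are not given in the sources used here. Gene identifiers were matched to GENCODE M21 gene names, which cover 52081 of the 55414 identifiers; the unmatched ones took a median of 0.538% of counts in epithelial libraries and 0.560% in tissue libraries, at most 1.55%. That annotation follows an earlier build than the counts, so no coordinates are given. Genotype, day, replicate, sequencing batch and library series were taken from the labels. Total counts were 33830001 to 46245422 per epithelial library and 29482454 to 52681593 per tissue library. A gene with no counts in a whole group is compared against a floor of 3 counts over that group, which covers counting error only.

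Genes were filtered with filterByExpr in edgeR 4.0.16 (minimum count 10, minimum total 15), leaving 18737 in epithelial cells and 19526 in tissue, and scaled by trimmed mean of M values (TMM). Each of 10 comparisons used an edgeR quasi-likelihood F test with a spread shared by the 4 groups of its kind of material: Tg against WT in each condition, DSS or day 8 against control or day 0 in each genotype, and the genotype by treatment interaction. A batch term entered the epithelial comparisons and the tissue genotype and interaction comparisons. It was left out for tissue day comparisons, where batch nearly equals day. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called, and standard errors are the log2 fold change divided by the square root of F. Counts-per-million values (CPM) use TMM-scaled library sizes. RLE scaling moved the median change of all genes from 0.07 to 0.20 in the tissue interaction and from 0.10 to 0.20 for day in Tg tissue, and changes are given relative to the TMM scale.

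44 gene lists with 687 genes, covering epithelial cell types, other cell types of the colon, cell death, inflammation, interferon, stress, metabolism and transport, were part of the design. 42 lists with at least 5 tested members were tested with fry of limma 3.58.1 on voom values, Benjamini-Hochberg adjusted over the lists of a comparison. Fry tests whether the genes of a list move on balance one way and does not compare them with other genes. Camera, which does, was run with a preset correlation of 0.01 and with an estimated correlation. The groups entered the design in alphabetical order of their labels, capitals first, and 2 other orders were tried after the data were seen. Members were also adjusted over the list alone. No list passed by fry changed the sign of its median under the other scalings, and where genes had no counts in a whole group, putting them at their bound left the medians of the passed lists as they were. The list score of a library is the mean log2 CPM of the tested members (prior count 1). The genes followed by name in each comparison were Casp3, Casp7 and Gsdmd, the 8 called genes with the largest rise and the 8 with the largest fall at a mean of at least 2 CPM (without predicted genes, pseudogenes, immunoglobulin and T cell receptor segments, Xist and Y-linked genes), and for each list up to 4 called members with the smallest p, or up to 2 members where none was called.

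Alternatives planned with the design were DESeq2 1.42.0, limma voom with quality weights, RLE and upper-quartile scaling, no low-count filter, a filter at 1 CPM, the batch term removed or added, a block by replicate number, Xist or the library series as covariates, single batches, a fit to the 2 groups of a comparison alone, calls also changed by 1 or more on the log2 scale, and each library left out in turn. After the data were seen, fits without the 4 squamous libraries, without these and WT day 0 library 1, and with day 8 libraries of series DSS11 only were added. Computation used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Every library and column deposited entered the comparisons. Among 92 pairs of libraries within groups none were identical. Whether replicate numbers pair the libraries is uncertain. In the epithelial DSS genotype comparison correlations between libraries with the same number ranged from -0.117 to 0.539. There 4 of 6 exceeded 0.1 and 4 of 6 were highest with their own number. For DSS in Tg cells 3 of 4 exceeded 0.1 and 3 of 4 were highest with their own number. For day in WT and in Tg tissue 0 of 5 exceeded 0.1.

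The fits were tested on simulated data with the real means, depths and spread and 200 changed genes. In epithelial comparisons of 2 groups 25.4% to 43.1% of genes changed by 1.5-fold, 63.4% to 71.2% of those changed by 2-fold and 77.8% to 88.3% of those changed by 4-fold were called. In tissue comparisons of 2 groups 0% of 1.5-fold changes, 0% to 2.70% of 2-fold changes and 22.6% to 46.5% of 4-fold changes were called, so tissue comparisons detect mainly large changes. In the interaction tests 7.20%, 42.6% and 70.0% of 1.5-, 2- and 4-fold changes were called in epithelial cells, and 0%, 0% and 2.70% in tissue. At most 11 genes were called falsely in any comparison, and none with the wrong sign. The simulation held no batch effect and no structure shared by many genes, such as squamous libraries. False calls in the real libraries may therefore be more.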

Results

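RNA sequencing compared wild-type mice (WT) with their littermates labelled Tg, described in the series as Casp3/7 transgenic, during damage by dextran sulphate sodium (DSS), a polysaccharide in drinking water that injures the colonic epithelium. The study asks how caspases 3 and 7, the executioner proteases of apoptosis, affect intestinal inflammation, stem cell genes and pyroptosis, the lytic cell death carried out by the pore protein encoded by Gsdmd. 2 kinds of material were sequenced. Homogenised distal colon gave 22 libraries, with 5 WT and 6 Tg libraries at day 0, and 6 WT and 5 Tg libraries at day 8, after 5 days of 3% DSS and 3 days of water. Intestinal epithelial cells, from a part of the gut that the labels do not give, yielded 20 libraries, with 4 WT and 4 Tg control libraries, and 6 WT and 6 Tg libraries at day 3 of 3% DSS. The total count per library was 33830001 to 46245422 for epithelial cells and 29482454 to 52681593 for tissue. Changes below are log2 fold changes ± standard error, and levels are mean counts-per-million values (CPM) ± SD over the libraries of a group. The gene lists, and the rule that picked the genes followed by name, were fixed before the data were examined. Detection floors cover counting error only, while SDs and standard errors include the spread between libraries.

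Some libraries stood apart before any comparison. 4 tissue libraries (WT day 0 library 5, WT day 8 library 2, Tg day 8 libraries 1 and 2) held transcripts of stratified squamous epithelium, the lining of the anal canal: Krt5, a basal keratin, reached 273 to 8610 CPM in them and at most 1.30 CPM in the other 18. Summed over 14 squamous markers, chosen after the data were seen, these libraries had 2907 to 36392 CPM, against 1.46 to 88.1 CPM in the rest. Tissue results are therefore also given without these 4 libraries, a comparison chosen after seeing the data. Ddx3y, a Y-linked gene, was counted at 1 CPM or more in 8 of the 22 tissue libraries: 2 of 5 WT and 3 of 6 Tg at day 0, and 2 of 6 WT and 1 of 5 Tg at day 8. It had no counts in the 20 epithelial libraries, where Xist, the transcript of the inactive X chromosome, was at 491 to 1005 CPM.

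Casp3 and Casp7 were both lower in Tg epithelial cells in each condition; the labels give neither the construct nor the cells it acts in. Casp3 was at 8.24 ± 1.32 CPM against 48.8 ± 3.47 CPM in Tg and WT control cells, a change of -2.57 ± 0.13 (n = 4 and 4, adjusted p = 1.15e-09), and at 9.96 ± 1.25 CPM against 46.4 ± 6.34 CPM under DSS, a change of -2.22 ± 0.11 (n = 6 and 6, adjusted p = 3.42e-10). Casp7 changed by -1.40 ± 0.14 in control cells (52.0 ± 7.23 CPM against 137 ± 10.4 CPM, adjusted p = 5.15e-05) and by -1.21 ± 0.12 under DSS (68.2 ± 8.02 CPM against 160.0 ± 34.9 CPM, adjusted p = 2.16e-05). For both genes every Tg library was below every WT library in both conditions. In day 0 tissue Casp3 was at 5.35 ± 1.35 CPM against 61.7 ± 49.8 CPM, a change of -3.53 ± 0.48 (n = 6 and 5, adjusted p = 0.00757). Casp7 there was at 38.6 ± 9.31 CPM against 109.8 ± 33.5 CPM, with every Tg library below every WT library, but missed the threshold (adjusted p = 1.00). In day 8 tissue Casp7 changed by -3.32 ± 0.50 (n = 5 and 6, adjusted p = 0.00661), while Casp3 was at 28.2 ± 16.4 CPM against 34.9 ± 13.7 CPM (adjusted p = 0.719). Within Tg tissue Casp3 was higher at day 8 than at day 0, by 2.40 ± 0.45 (adjusted p = 0.000678). The genotype by day interaction of Casp3, 3.19 ± 0.66, did not pass (adjusted p = 0.111).

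**Figure D1:**
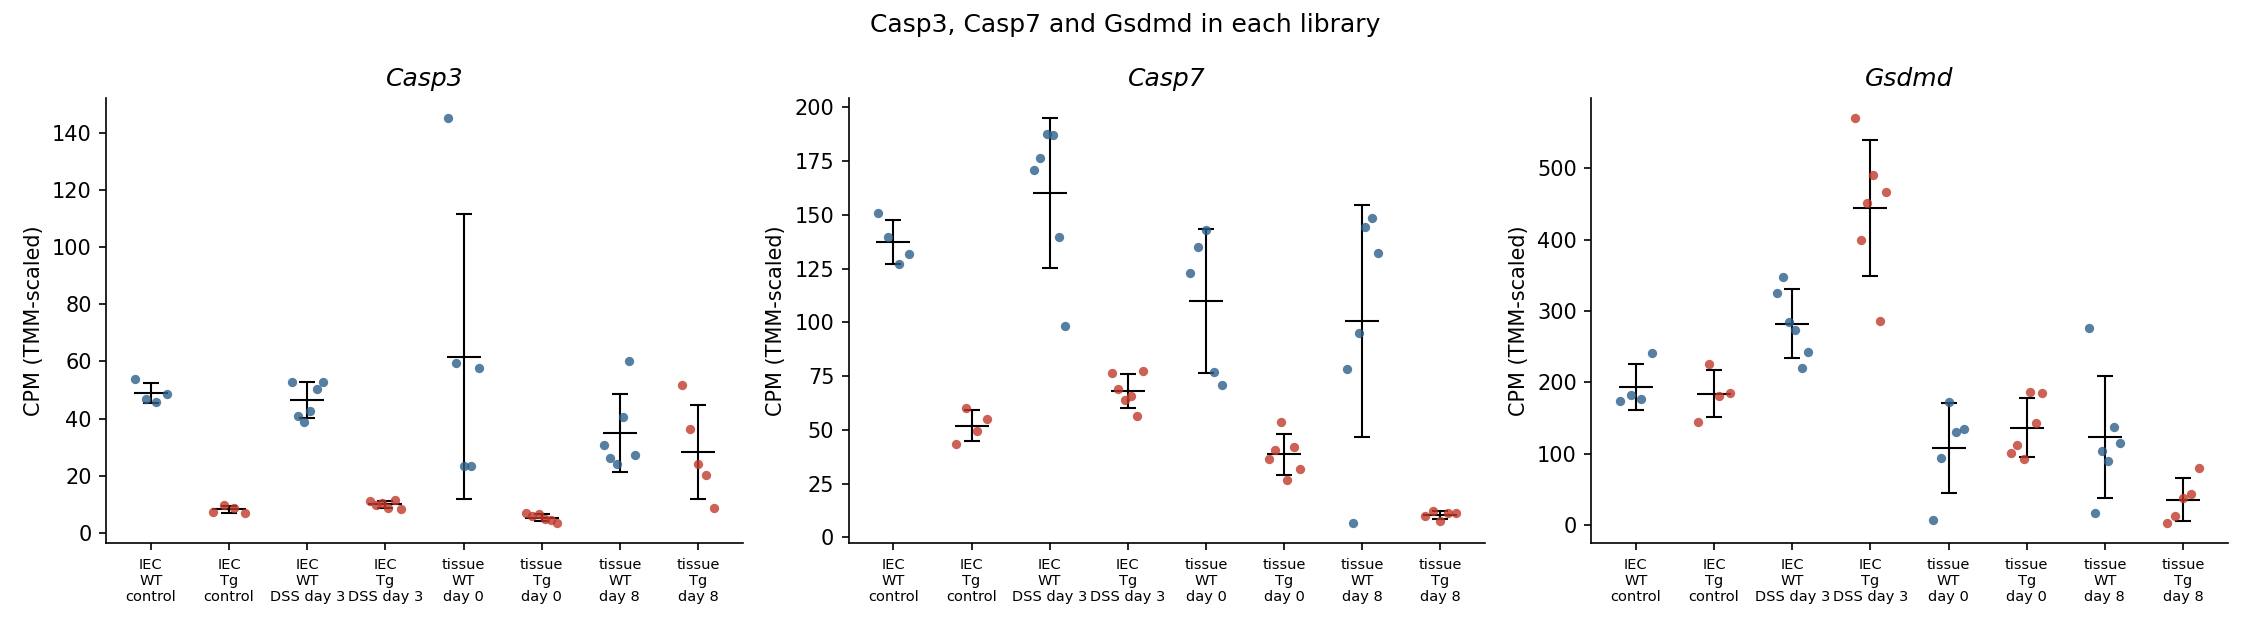
Counts-per-million values of Casp3, Casp7 and Gsdmd in each library (points), by group, with WT in blue and Tg in red. Bars give the mean ± SD of a group, and Tg epithelial libraries lie below all WT epithelial libraries for Casp3 and Casp7.

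Without DSS, epithelial cells of the genotypes differed in few genes. 14 of 18737 tested genes passed, 11 higher and 3 lower in Tg. Mt1, a metal-binding metallothionein, was at 304 ± 15.9 CPM against 79.6 ± 9.78 CPM (1.93 ± 0.26, n = 4 and 4, adjusted p = 0.00247). The secreted lectin Itln1 (3.66 ± 0.58), the pancreatic-type lipase Pnliprp2 (2.99 ± 0.45) and the stress-inducible Gadd45g (2.17 ± 0.35) rose, and the laminin chain Lama5 fell (-1.16 ± 0.21). Of 14 endoplasmic reticulum stress genes, 9 rose adjusted over the list alone and 0 over all genes, and theirs was the single list past the threshold (adjusted p = 0.0446, and adjusted p = 0.567 with an estimated correlation). This call depended on the numerical order of the groups in the design (adjusted p = 0.0433 and 0.0550 in 2 other orders) and was lost without the batch term (adjusted p = 0.0871). The 11 tested markers of tuft cells, chemosensory cells of the epithelium, had a median of 1.22, and 11 passed adjusted over the list alone and 0 over all genes. The tuft cell list was near the threshold (adjusted p = 0.0608, and 0.0433 and 0.0567 in the other orders), as was the apoptosis list (adjusted p = 0.0608), whose members past the threshold over all genes were Casp3 and Casp7. T and natural killer cell markers were higher in Tg, 15 of 18 adjusted over the list alone and 0 over all genes, but the list did not pass (adjusted p = 0.155).

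The count of 14 depended on the settings and on single libraries: DESeq2, run without the low-count filter, gave 167, limma voom with quality weights 3460, edgeR with no low-count filter 69 and a fit to these 8 libraries alone 34. It was 443 without Tg control library 2 and 3 to 5 without WT control library 1, 2, 3 or 4 or Tg control library 1 or 3, and of the 11 called genes followed by name only Casp3, Casp7 and Mt1 passed without each single library of these groups. With Xist as a covariate Casp3 and Casp7 were the 2 genes called and Mt1 did not pass (adjusted p = 0.0560).

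Under DSS, epithelial cells of the genotypes differed in many genes. 2052 of 18737 genes passed at day 3, 1058 higher and 994 lower in Tg (n = 6 and 6). Antimicrobial genes rose, 12 of 17 over all genes and 16 adjusted over the list alone, with a median of 1.44 (adjusted p = 0.00283, and adjusted p = 0.155 with an estimated correlation). The antibacterial lectin Reg3b was at 231 ± 356 CPM against 0.110 ± 0.114 CPM (10.98 ± 1.65, adjusted p = 0.00561), its relative Reg3g changed by 8.33 ± 1.34 and the goblet cell protein Retnlb by 4.26 ± 0.88. Genes of regenerating or fetal-like epithelium rose, 11 of 21 over all genes and 16 adjusted over the list alone (adjusted p = 0.00250, and adjusted p = 0.155 with an estimated correlation), among them Emp1, a membrane protein (424 ± 340.5 CPM against 78.7 ± 47.4 CPM, 2.31 ± 0.46), Ly6a (1.42 ± 0.28), the growth factor Areg (1.21 ± 0.23) and the urokinase receptor Plaur (1.18 ± 0.22). Stem cell genes fell on balance, with 5 lower and 1 higher of 17 (adjusted p = 0.0222, and adjusted p = 0.270 with an estimated correlation): Smoc2 changed by -1.32 ± 0.24, Lrig1 by -0.58 ± 0.10 and Slc12a2 by -0.62 ± 0.12, while Prom1 rose by 1.33 ± 0.24. The differentiation keratin Krt20 rose by 1.27 ± 0.24 and, in the absorptive cell list, 9 of 21 genes rose (adjusted p = 0.0120, and adjusted p = 0.189 with an estimated correlation). Cps1, a urea cycle enzyme, changed by -1.76 ± 0.33, the lectin Reg4 by -1.96 ± 0.39 and the chloride channel Cftr by -0.78 ± 0.14.

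Pyroptosis and inflammasome genes rose in Tg cells at day 3, 8 of 22 over all genes, with 10 higher and 2 lower adjusted over the list alone (median 0.23, adjusted p = 0.00283, and adjusted p = 0.155 with an estimated correlation). Gsdmd was at 444 ± 95.5 CPM against 282 ± 48.2 CPM (0.66 ± 0.13, adjusted p = 0.0102), the cytokine Il1b changed by 2.15 ± 0.42 and the inflammasome sensor Nlrp3 by 1.95 ± 0.39. Of 12 cytokine and NF-kB genes 4 rose (adjusted p = 0.00678, and adjusted p = 0.187 with an estimated correlation), including Tnf (1.15 ± 0.19), and of 16 chemokine genes 4 rose and 1 fell (adjusted p = 0.00386, and adjusted p = 0.155 with an estimated correlation). Markers of other cell types moved the same way: 11 of 12 neutrophil genes (S100a8 at 2.22 ± 1.88 CPM against 0.242 ± 0.150 CPM), 13 of 19 monocyte and macrophage genes, 4 of 5 red cell genes, 3 of 13 endothelial genes and 3 of 11 smooth muscle genes rose (adjusted p = 0.00250, 0.00283, 0.0222, 0.0222 and 0.0472). With an estimated correlation these 5 lists had adjusted p = 0.155, 0.166, 0.248, 0.248 and 0.270. The last 3 did not pass without the batch term (adjusted p = 0.0924, 0.0617 and 0.0998), and the smooth muscle list missed the threshold in 1 of 2 other orders of the groups in the design (adjusted p = 0.0502). Lists of hypoxia and glycolysis (8 of 15 rose), general epithelial markers (6 of 16), matrix remodelling (5 of 15), type I interferon (5 of 27), necroptosis (3 of 7) and tuft cells (3 of 11) passed upward too, and ribosomal protein genes passed downward (5 of 22). In all 23 of 42 lists passed, 21 up and 2 down, and 17 of them passed without the batch term; with an estimated correlation none passed, their adjusted p = 0.155 to 0.289.

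**Figure D2:**
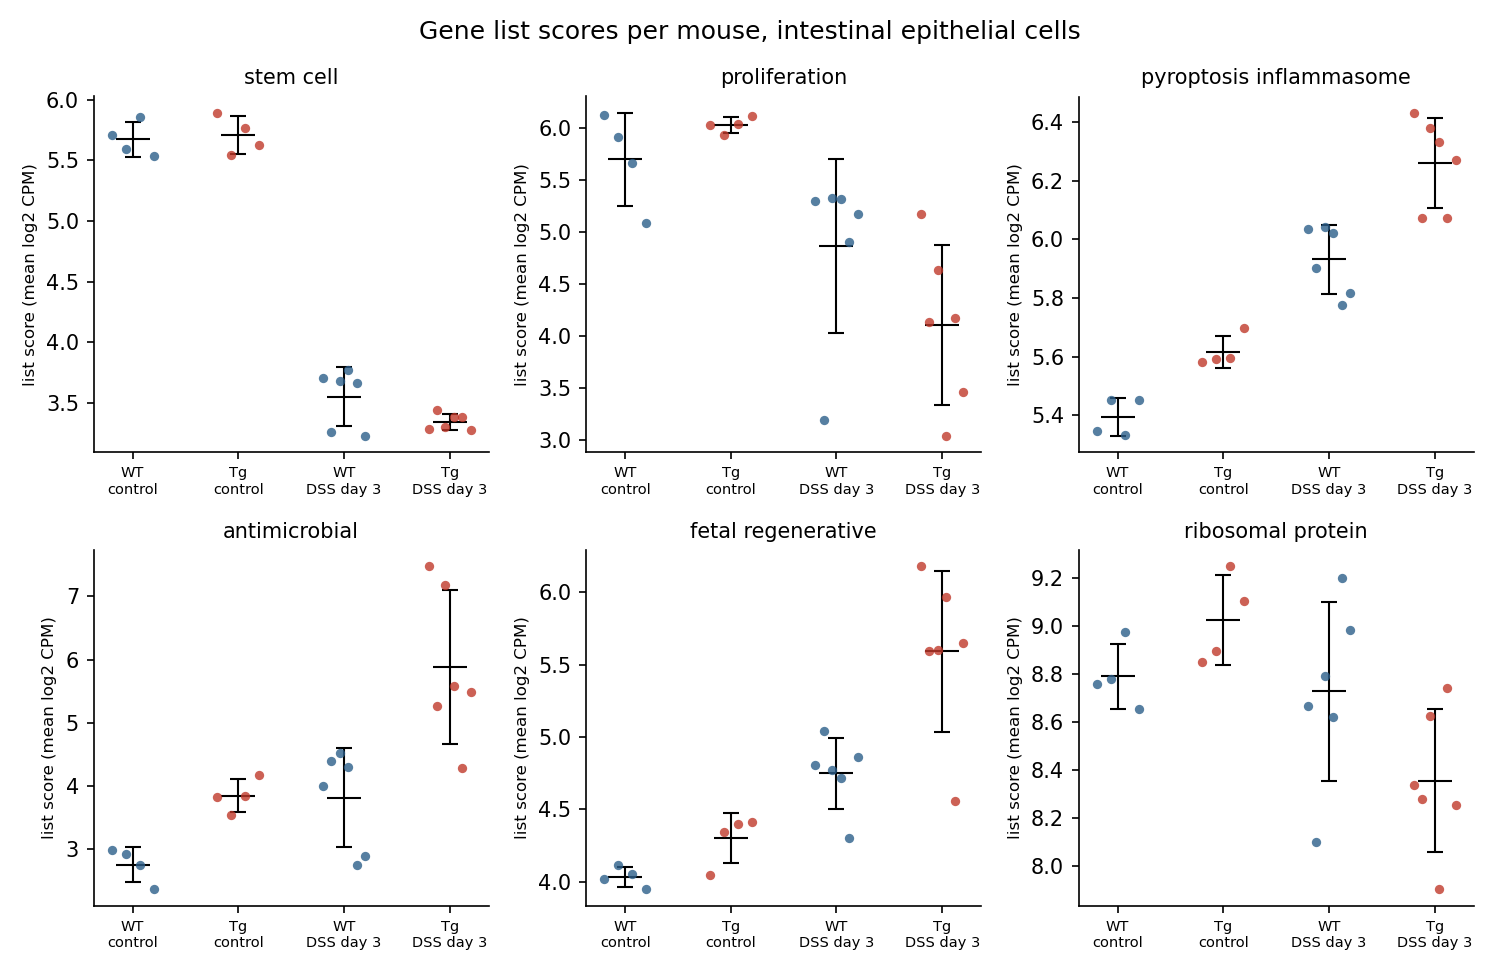
Mean log2 CPM of the members of chosen gene lists in each epithelial library (points), by group, with WT in blue and Tg in red. Bars give the mean ± SD of a group.

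Of the 115 called genes followed by name at day 3 of DSS, 34 passed without each single library of these groups, and the genes just named are among them. The count of 2052 was 691 within batch 1 (n = 4 and 4) and 30 within batch 2 (n = 2 and 2), 984 without the batch term and 3 in a fit to these 12 libraries alone. It fell to 289 without Tg DSS library 6, to 726, 732, 805 and 1228 without WT DSS library 5, 4, 3 or 1 and to 1346 without Tg DSS library 1, and rose to 3276 without Tg DSS library 5. Over the antimicrobial and regenerative genes the median change was 1.15 within batch 1 and 0.89 within batch 2. With Xist as a covariate the count was 76; Xist itself was at 619 ± 133 CPM in Tg and 746 ± 77.4 CPM in WT cells under DSS, so this covariate overlaps with genotype.

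DSS itself lowered stem cell and Wnt target genes in WT epithelial cells. 2626 genes passed between day 3 and control in WT, 1240 higher and 1386 lower (n = 6 and 4). The stem cell marker Lgr5 changed by -6.60 ± 0.32 (0.158 ± 0.0811 CPM against 18.3 ± 4.30 CPM) and Ascl2, a transcription factor of stem cells, by -6.33 ± 0.56. Of 17 stem cell genes 14 fell (adjusted p = 3.28e-10, and adjusted p = 0.00175 with an estimated correlation). Of 13 Wnt targets 7 fell, Axin2 by -4.89 ± 0.30 (adjusted p = 1.57e-08, and adjusted p = 0.00545 with an estimated correlation). Pyroptosis genes rose, 12 of 22 (adjusted p = 9.74e-06, and adjusted p = 0.0200 with an estimated correlation), with Gsdmd at 282 ± 48.2 CPM against 193 ± 32.2 CPM (0.66 ± 0.15), Gsdmc4 up by 1.16 ± 0.18, Casp4, the sensor of cytosolic lipopolysaccharide, by 0.97 ± 0.15 and the cytokine Il18 by 0.91 ± 0.16. The protease inhibitor Slpi rose by 3.93 ± 0.48 and Tnf by 2.50 ± 0.24, while the replication helicase gene Mcm4 changed by -1.45 ± 0.22 and the pore-forming claudin Cldn2 by -2.48 ± 0.60. Regenerative (12 of 21 rose), monocyte and macrophage (13 of 19), chemokine (5 of 16), antimicrobial (6 of 17), neutrophil (6 of 12), goblet cell (5 of 14), fatty acid oxidation (2 of 19) and oxidative phosphorylation genes (3 of 20) were among the 13 lists that rose. With an estimated correlation the lists other than the first 3 had adjusted p = 0.0909 to 0.458. Of the 15 lists passed 10 passed without the batch term, the antimicrobial and neutrophil lists not among them (adjusted p = 0.294 and 0.389). All control libraries were of batch 1, and the count was 1947 against the batch 1 DSS libraries alone, 1532 without WT control library 3, 1597 without WT control library 2, 5587 with limma voom quality weights and 1750 without the batch term.

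In Tg epithelial cells DSS changed more genes, 8182, with 3992 higher and 4190 lower (n = 6 and 4). Lgr5 changed by -6.30 ± 0.33, Ascl2 by -7.80 ± 0.59 and Smoc2 by -4.29 ± 0.28, and of 17 stem cell genes 13 fell and 1 rose (adjusted p = 6.87e-11, and adjusted p = 0.0248 with an estimated correlation). All 24 cell cycle genes fell (median -1.69, adjusted p = 0.000444, and adjusted p = 0.265 with an estimated correlation), Mcm2 by -1.79 ± 0.23, as did all 22 ribosomal protein genes (median -0.81, adjusted p = 0.000615, and adjusted p = 0.296 with an estimated correlation) and 8 of 13 Wnt targets (adjusted p = 0.0916 with an estimated correlation), Myc by -1.71 ± 0.16. Antimicrobial (14 of 17), neutrophil (12 of 12), regenerative (19 of 21), absorptive (16 of 21) and pyroptosis genes (15 of 22) rose, with Reg3b at 231 ± 356 CPM against 0.0921 ± 0.109 CPM, Slpi up by 5.30 ± 0.52, Il1b by 4.06 ± 0.56, Gsdmd by 1.39 ± 0.16 and Naip1, a sensor of bacterial proteins, by 1.33 ± 0.16. With an estimated correlation these 5 lists had adjusted p = 0.0916 to 0.261. Prss22, a serine protease with no counts in Tg control cells, was at least 233-fold higher against a floor of 3 counts over that group. Fibroblast (8 of 13), enteroendocrine (9 of 13), junction (13 of 16), ion transport (8 of 16), immediate early (8 of 12) and YAP target genes (5 of 9) were among the 28 lists that passed, 24 up and 4 down. With an estimated correlation the lists other than the stem cell list had adjusted p = 0.0916 to 0.449, and 26 of the 28 passed without the batch term. A fit to these 10 libraries alone called 5255 genes.

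The response to DSS was not shown to differ between genotypes gene by gene. In the interaction test edgeR called 0 of 18737 genes, with 3542 at an unadjusted p under 0.05, DESeq2 called 345 and limma voom with quality weights 3510. Gsdmd rose by 0.66 ± 0.15 in WT and 1.39 ± 0.16 in Tg, and its interaction of 0.73 ± 0.21 passed adjusted over the pyroptosis list alone (adjusted p = 0.0158) but not over all genes (adjusted p = 0.152). No gene list passed, the nearest being general epithelial markers, enteroendocrine cells and absorptive cells (adjusted p = 0.131, 0.131 and 0.131). Without WT DSS library 2 the count was 361, without Tg DSS library 3 it was 16, without Tg DSS library 5 it was 10, and it was 3 and 1 without Tg control library 2 and WT control library 3.

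In uninjured tissue at day 0, interferon-stimulated genes were higher in Tg. Of 27 type I interferon genes 17 rose adjusted over the list alone and 0 over all genes, with a median of 1.61 (adjusted p = 0.0356, and adjusted p = 0.00780 with an estimated correlation, n = 6 and 5). Usp18, a regulator of interferon signalling, was at 9.49 ± 8.32 CPM against 1.30 ± 0.467 CPM (2.86 ± 0.52, adjusted over the list alone to an adjusted p = 0.000489). Ifi44 changed by 3.76 ± 0.73 (adjusted over the list alone to an adjusted p = 0.000615). Of 27 genes of interferon gamma response and antigen presentation 6 were higher adjusted over the list alone, and that list did not pass (adjusted p = 0.280). Lymphocyte markers had higher list scores in Tg too. T and natural killer cell markers had a median of 1.59 and B and plasma cell markers of 1.96, and their list scores differed by 1.58 and 2.75 (exact two-sided permutation p = 0.00649 for each over 462 arrangements, tested after the data were seen). Of these markers 0 of 18 and 0 of 17 passed, and neither list did (adjusted p = 0.953 for each). Casp3 was the single gene past the threshold over 19526 genes, with 412 at an unadjusted p under 0.05, and DESeq2 called 130 and limma voom with quality weights 342. The type I interferon score differed by 1.74 in library series DSSIEC12 (3 Tg, 2 WT) and by 1.91 in series DSSIEC2 (3 Tg, 3 WT), an exact permutation within series giving p = 0.01 (two-sided, 200 arrangements). The list passed without the squamous libraries (adjusted p = 0.000457), where the interferon gamma list passed too (adjusted p = 0.00296). The type I interferon list passed neither without the batch term (adjusted p = 0.176) nor with a block by replicate number. Casp3 did not pass in a fit to these 11 libraries alone, which called 0 genes.

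At day 8, after DSS and recovery on water, Tg tissue had lower levels of genes of mature colonic epithelium. 998 of 19526 genes passed, 225 higher and 773 lower (n = 5 and 6). WT day 8 library 1 was the sole day 8 library of batch 2, so it sets the batch term and adds nothing to this difference, which rests on 5 and 5 libraries (1002 genes without it, 996 of them shared). Goblet cell genes fell, 13 of 14 over all genes and 14 adjusted over the list alone (median -5.59, adjusted p = 0.0307, and adjusted p = 0.241 with an estimated correlation), among them Spink4 by -6.15 ± 1.30 and Bcas1 by -4.08 ± 0.72. Absorptive cell genes fell, 7 of 21 over all genes and 19 adjusted over the list alone (median -3.72, adjusted p = 0.0222, and adjusted p = 0.241 with an estimated correlation): the cytochrome P450 gene Cyp2c55 was at 0.264 ± 0.367 CPM against 242 ± 411 CPM (-10.04 ± 1.63, adjusted p = 0.00734) and the carbonic anhydrase Car4 changed by -5.01 ± 0.78. Ion transport genes fell (6 of 16, adjusted p = 0.0256, and adjusted p = 0.241 with an estimated correlation), including the sulphate transporter Slc26a2 (-2.58 ± 0.47) and the butyrate transporter Slc5a8 (-5.32 ± 0.97). Xenobiotic metabolism genes fell too (5 of 15, adjusted p = 0.0222, and adjusted p = 0.241 with an estimated correlation), including the carboxylesterase Ces2a (-7.76 ± 1.06). Oxidative phosphorylation genes fell (8 of 20, 17 adjusted over the list alone, adjusted p = 0.00296, and adjusted p = 0.241 with an estimated correlation), including Cox7a2 (-1.41 ± 0.28). Ang4, an antimicrobial ribonuclease, changed by -7.53 ± 1.34. Malrd1 and Ugt2b5 had no counts in Tg day 8 libraries and were at least 816-fold and 398-fold lower there against a floor of 3 counts over the group. General epithelial markers (1 of 16 fell), junctions (2 of 16), small intestinal enterocyte genes (1 of 7) and apoptosis genes (2 of 24, including Casp7) also passed downward, each with adjusted p = 0.241 with an estimated correlation.

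Matrix and fibroblast genes were higher in Tg tissue at day 8, relative to the other transcripts. The general epithelial list score was lower there, at 4.55 ± 2.77 in Tg against 8.39 ± 2.15 in WT. CPM values are shares of a library, so a changed share of cell types was not separated from a change within cells. Matrix remodelling (2 of 19 over all genes, 13 adjusted over the list alone) and fibroblast genes (3 of 14 over all genes, 11 adjusted over the list alone) rose, including the collagen cross-linking enzyme Lox (2.21 ± 0.58) and the fibroblast receptor Pdgfra (2.08 ± 0.50). These 2 lists had adjusted p = 0.241 and 0.275 with an estimated correlation, and neither passed without the batch term (adjusted p = 0.0563 and 0.0858). Endothelial, neutrophil, YAP target and Wnt target lists passed upward with no member past the threshold over all genes. In all 15 of 42 lists passed, 6 up and 9 down, and with an estimated correlation their adjusted p = 0.241 to 0.334. Without the batch term 10 of them passed, the endothelial, neutrophil and YAP target lists being lost too (adjusted p = 0.0563, 0.0563 and 0.0927). Without the squamous libraries (3 Tg and 5 WT) 3679 genes passed, 2093 higher and 1586 lower, with 986 of the 998 among them, and all 15 lists passed in the same direction. In this fit WT day 8 library 1 again only set the batch term, so the difference rests on the libraries of series DSS11. There, neutrophil genes rose (14 of 18, median 3.45), as did monocyte and macrophage (11 of 19), matrix remodelling (17 of 19), endothelial (12 of 13) and cytokine genes (8 of 15). Goblet cell genes fell (14 of 14), as did pyroptosis genes, of which 14 fell and 3 rose of 22. Gsdmd was at 35.5 ± 30.0 CPM against 123.1 ± 85.4 CPM over all libraries and did not pass (adjusted p = 0.231).

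**Figure D3:**
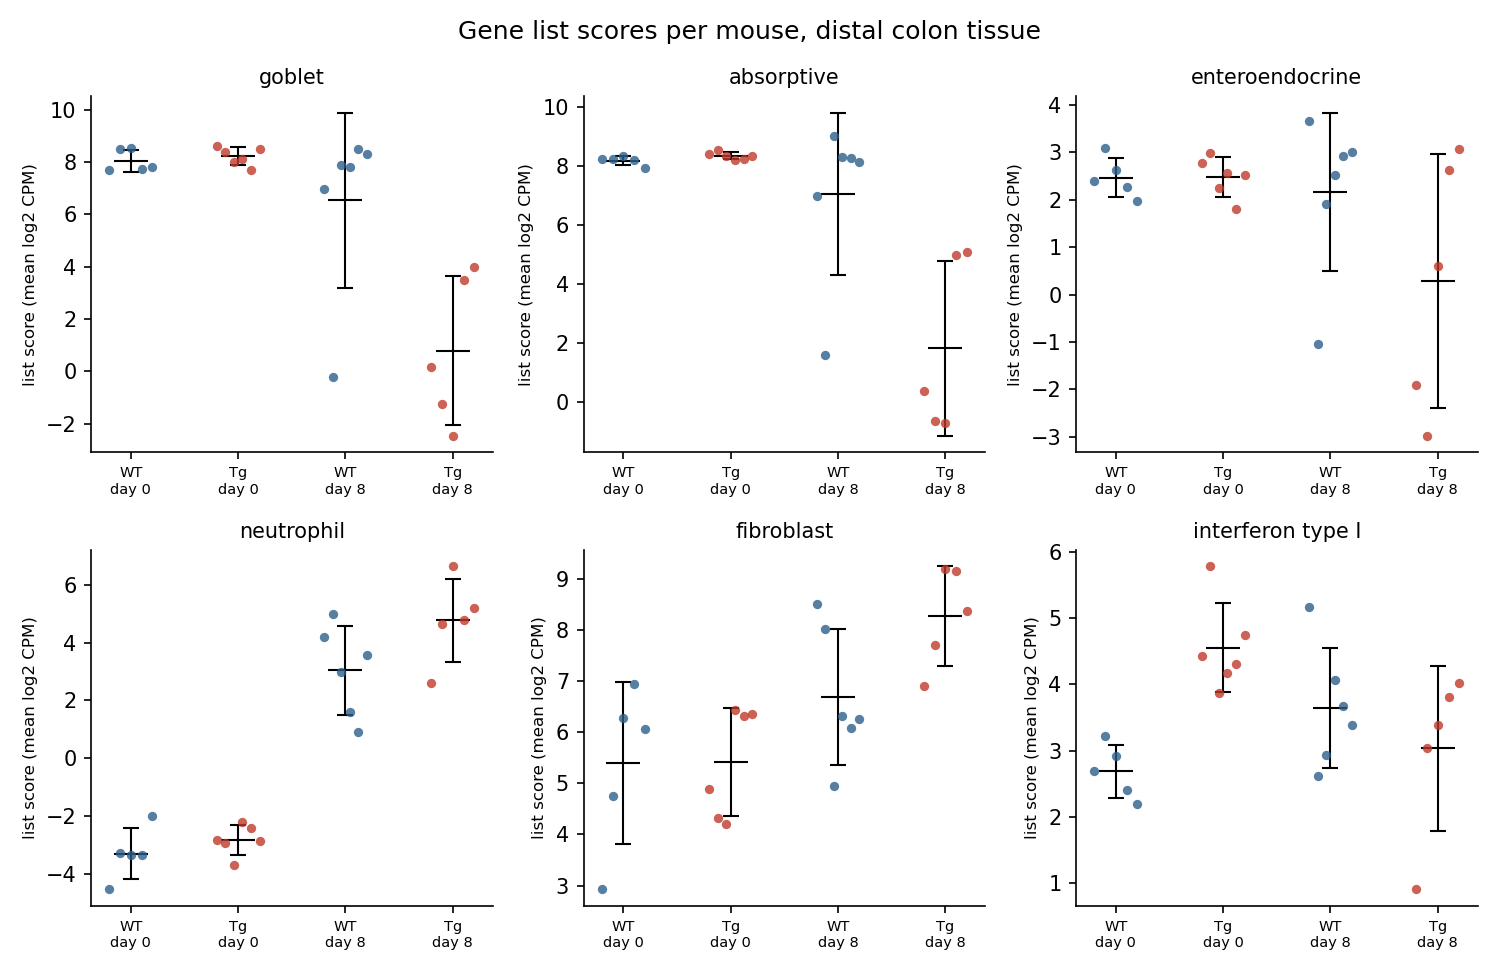
Mean log2 CPM of the members of chosen gene lists in each tissue library (points), by group, with WT in blue and Tg in red. Bars give the mean ± SD of a group.

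Of the 67 called genes followed by name in day 8 tissue, 16 passed without each single library of these groups. Among the genes just named, Lox and Pdgfra did not pass without WT day 8 library 3, 4, 5 or 6 or Tg day 8 library 3 or 4, and Malrd1 and Ugt2b5 also lost their call without single libraries, among them Tg day 8 library 3 (the others passed without each). The count was 3825 without WT day 8 library 2, between 132 and 495 without Tg day 8 library 2, 3 or 4 or WT day 8 library 3, 4, 5 or 6. It was 505 without the batch term, 4 with a block by replicate number, 633 with no low-count filter, 2704 with DESeq2, 7272 with limma voom quality weights and 0 in a fit to these 11 libraries alone, where 4083 genes had an unadjusted p under 0.05.

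From day 0 to day 8, WT tissue gained inflammatory transcripts. 943 genes passed, 694 higher and 249 lower (n = 6 and 5). Neutrophil genes rose (15 of 18, median 7.19, adjusted p = 0.00738, and adjusted p = 0.216 with an estimated correlation): S100a8, a subunit of calprotectin, changed by 9.27 ± 1.36, and Retnlg, with no counts at day 0, was at least 2041-fold higher against 3 counts over the group. Matrix remodelling genes rose (14 of 19, adjusted p = 0.0143, and adjusted p = 0.216 with an estimated correlation), including the stromelysin Mmp10 (8.23 ± 1.42). The lists that rose also held those of cytokine (10 of 15, Il11 by 6.98 ± 1.28), chemokine (10 of 19, Cxcl5 by 5.83 ± 0.97), antimicrobial (9 of 18, Lcn2 by 6.05 ± 0.92 and Saa3 by 11.92 ± 1.52), regenerative (7 of 24, Ly6a by 2.46 ± 0.32) and endoplasmic reticulum stress genes (1 of 14). With an estimated correlation these 5 lists had adjusted p = 0.216 to 0.407. Reg3b had no counts in the WT day 0 libraries and reached 2261 CPM at day 8. Mptx1, a pentraxin of the colonic epithelium, changed by -8.50 ± 1.21 and the sugar phosphate transporter Slc37a2 by -4.36 ± 0.58. 7 lists passed, all up, and 6 of them with a batch term (endoplasmic reticulum stress genes, adjusted p = 0.0525).

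In Tg tissue the change from day 0 to day 8 covered 6585 genes, 3701 higher and 2884 lower (n = 5 and 6). Neutrophil (17 of 18), matrix remodelling (19 of 19), endothelial (12 of 13), fibroblast (11 of 14), enteric neuron and glia (12 of 13) and red cell genes (5 of 5) rose, with S100a8 up by 13.01 ± 1.47, Lcn2 by 8.31 ± 0.94 and the stromal Grem1 by 4.33 ± 0.65. These 6 lists had adjusted p = 0.295 to 0.416 with an estimated correlation. Goblet (13 of 14), absorptive (16 of 21), ion transport (12 of 16), oxidative phosphorylation (16 of 20), cholesterol synthesis (9 of 19) and pyroptosis genes (15 of 22, against 3 that rose) fell. The latter 6 had adjusted p = 0.295 to 0.379 with an estimated correlation. The goblet cell protein Clca1 changed by -7.58 ± 1.44, the water channel Aqp8 by -8.18 ± 1.65, Lgr5 by -3.32 ± 0.70 and Casp1, which activates Il1b and Gsdmd, by -2.86 ± 0.54. Type I interferon genes fell, 13 of 27, Irf7 by -2.88 ± 0.58 (adjusted p = 0.0175, and adjusted p = 0.416 with an estimated correlation). Their list did not pass without the squamous libraries, where 10 fell (adjusted p = 0.0645), and went the other way with a batch term (adjusted p = 0.733). Krt5 rose by 15.55, and the keratinised-epithelium gene Cnfn, with no counts at day 0, was at least 9402-fold higher, in a group where Tg day 8 libraries 1 and 2 carried the squamous transcripts. 26 of 42 lists passed, 12 up and 14 down, 24 of them without the squamous libraries, and with an estimated correlation their adjusted p = 0.295 to 0.468. With a batch term 16 of the 26 passed. All 10 lost were lists that fell, among them absorptive, goblet, pyroptosis and stem cell genes (adjusted p = 0.0562, 0.0633, 0.111 and 0.223).

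**Figure D4:**
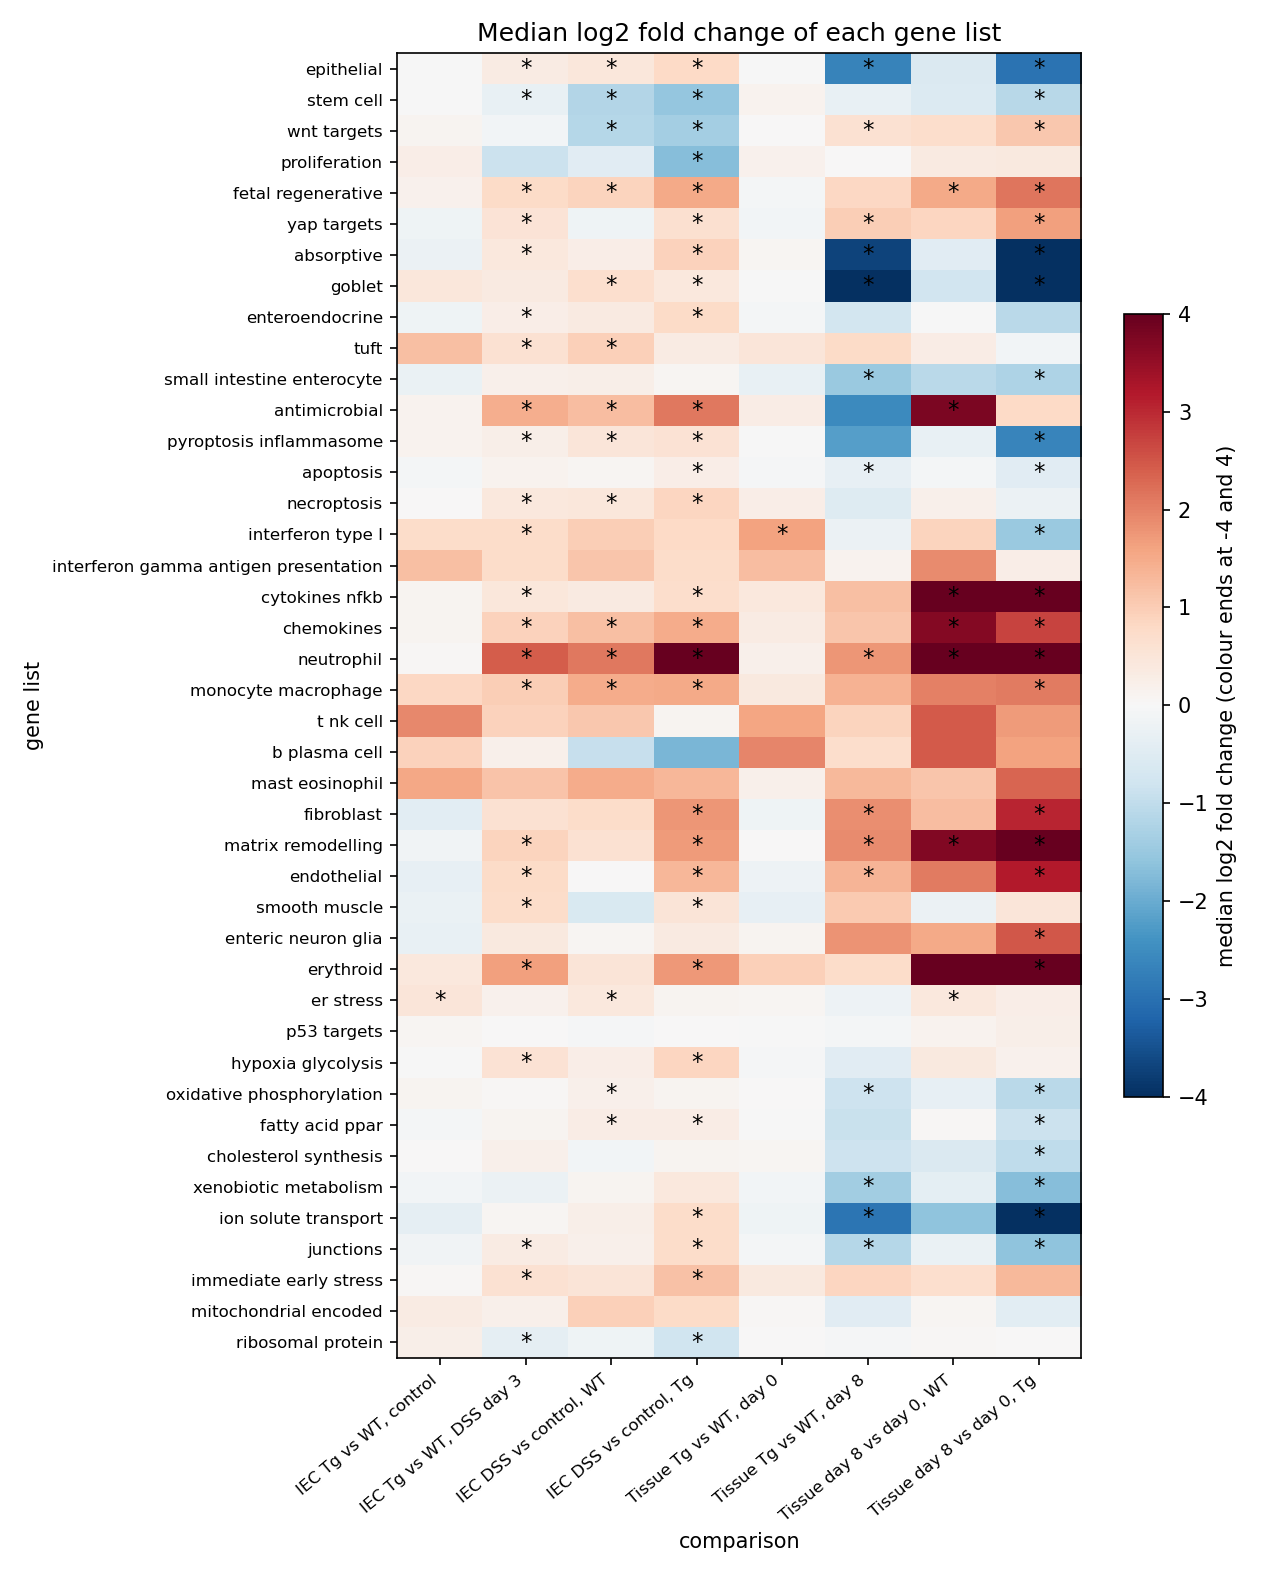
Median log2 fold change of each gene list in each comparison, on a colour scale that ends at -4 and 4. An asterisk marks lists past the threshold, adjusted p under 0.05 in the list test.

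Day and sequencing batch nearly coincide in tissue, since the day 0 libraries were all of batch 2 and WT day 8 library 1 was the sole day 8 library of that batch. A batch term, which rests on that library and its label, gave 861 calls in WT, of which 513 were also among the 943 and in the same direction. It gave 3328 in Tg, of which 2962 were also among the 6585 and 2961 in the same direction. The WT count was 538 without the squamous libraries, 394 to 620 without WT day 0 library 2, 3, 4 or 5 or WT day 8 library 1 or 2, 233 in a fit to these 11 libraries alone and 2089 with DESeq2, and the Tg count was 5926 without the squamous libraries.

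Whether the tissue response differed between genotypes depended on which libraries were kept. The interaction test called 0 of 19526 genes by edgeR, with 2925 at an unadjusted p under 0.05, against 537 by DESeq2 and 6149 by limma voom with quality weights. Cyp2c55 had an interaction of -9.31 ± 1.81 (adjusted p = 0.111), Ces2a of -7.46 ± 1.24 and Retnlb of -8.29 ± 1.93. These passed adjusted over the list alone of each (adjusted p = 0.000343, 9.09e-05 and 0.00262). No list passed over all libraries, oxidative phosphorylation being nearest (median -0.84, adjusted p = 0.0522). Without the squamous libraries 1562 genes and 18 lists passed, including goblet cell genes, of which 10 of 14 fell. The count was 1776 without WT day 8 library 2, 140 without Tg day 8 library 5, 1 without Tg day 8 library 4 and 90 with a library series term.

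Over all libraries 6 lists passed in no comparison: interferon gamma response and antigen presentation, T and natural killer cells, B and plasma cells, mast cells and eosinophils, p53 targets and mitochondrially encoded genes, with smallest adjusted p = 0.0564, 0.0744, 0.0867, 0.0704, 0.0856 and 0.0726 over the 10 comparisons. Without the squamous libraries T and natural killer cell genes passed upward at day 8 and for day in WT and Tg tissue (adjusted p = 0.0124, 0.00274 and 0.000305). Mast cell and eosinophil genes passed upward there for day in WT and Tg tissue (adjusted p = 0.0298 and 0.000920), as did the interferon gamma list at day 0 and for day in WT tissue (adjusted p = 0.00296 and 0.00274). Paneth cell and colon region lists had fewer than 5 tested members in both kinds of sample and were not tested. How reads shared between related genes were counted is not stated, which leaves the values of single members of the Reg3, Saa, Ifit, Gsdmc, Ly6, Sprr, Cyp2c, Ugt, Gbp and haemoglobin families uncertain.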

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

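The 7 tests of explanations in this part were chosen only after the results were seen. In 64 sets of values, each a measure in 1 group of libraries, the gap between the highest or lowest library and its nearest neighbour was set against the range of the group. 6 sets held a library far from the others, where chance gives about 1 in 20. Among 4 WT control epithelial libraries, library 4 had Gsdmd at 241.47 CPM against 174 to 182 CPM in the others, and library 1 had a type I interferon list score of 3.8564 against 2.701 to 2.73. Among 6 WT day 8 tissue libraries, library 4 had 18442 genes detected against 22684 to 23583, and library 2 had a goblet cell list score of -0.19754 against 6.97 to 8.48 and an epithelial list score of 4.1108 against 8.51 to 9.81. Among 5 WT day 0 tissue libraries, library 1 had an epithelial list score of 7.7348 against 9.38 to 9.75. It also had 16418 genes detected, the fewest of any tissue library, which this rule did not flag. Its log2 CPM values correlated at 0.780 to 0.833 with the other libraries of its group, against 0.928 to 0.970 among those.

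In day 8 tissue, goblet and absorptive cell genes were lower in Tg, with a median log2 fold change of -4.36. Squamous tissue in some libraries does not account for it: without the libraries over 100 CPM of Krt5 the median was -4.421. A loss of epithelial cells of every type alike would lower all epithelial markers by the same amount only if no other cells of the tissue expressed them. The goblet list score differed between genotypes by more than the general epithelial score, with a difference between them of -2.492 without those libraries (exact two-sided permutation p = 0.01786 over 56 arrangements, 3 Tg and 5 WT). Expression of the general markers in other cells was not measured, so this test cannot exclude such a loss. What stays open is a loss of epithelial cells of every type or of part of the epithelium, a change in the cells themselves, or damage of different severity in the few mice compared. A candidate explanation tied to genotype is that goblet and absorptive cells are more depleted in Tg mice after DSS, a hypothesis found on these libraries and not tested. Whether it extends to other differentiated cells was not settled. Without the squamous libraries tuft cell genes passed upward by fry (4 of 11 rose, median 0.90, adjusted p = 0.0257) and enteroendocrine genes did not pass (adjusted p = 0.513). Neutrophil and macrophage lists rose in the same fit, and expression of the tuft cell list in other cells was not measured. A list that did not pass does not show that its cells were spared. Over all libraries the enteroendocrine score was 0.287 ± 2.69 in Tg and 2.17 ± 1.67 in WT at day 8.

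In epithelial cells at day 3 of DSS, antimicrobial and regenerative genes were higher in Tg (median log2 fold change 1.16) while markers of neutrophils, macrophages, vessels and red cells rose too. A batch effect does not account for it: the median change of the pattern's genes was 1.15 in batch 1 and 0.8876 in batch 2. Additional immune and stromal cells in the preparation stay open: neutrophil and monocyte lists rose along with the pattern (medians 2.41 and 1.00), and the gain of such markers in CPM, 3.447% of that of the pattern's genes, depends on which genes are listed. In control cells the antimicrobial list score was already higher in Tg, at 3.54 to 4.18 against 2.37 to 2.99 in WT, though the list did not pass. Regenerative scores overlapped there (4.04 to 4.41 against 3.95 to 4.12). No list passed in the interaction test, so a genotype difference present before DSS stays open for the antimicrobial genes. Genotype may also act on the epithelial response to injury, or the mice may have differed in severity at day 3. The design holds no measure of severity that would separate a genotype effect from a difference in severity.

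In day 0 tissue, type I interferon genes were higher in Tg, by 1.87 on the list score (exact two-sided permutation p = 0.00216, 462 arrangements, 6 Tg and 5 WT). The library series do not account for it, since the smaller difference within a series was 1.745 (exact p = 0.01 over 200 arrangements within series). WT day 0 library 1, with its low epithelial score, does not account for it either: without it the difference was 1.872 (exact p = 0.004762, 210 arrangements). More lymphocytes in Tg tissue stay open: the score of the T, natural killer, B and plasma cell lists was higher by 2.148 (exact p = 0.004329), and its correlation with the interferon score within the genotypes was 0.524 (permutation p = 0.0820). Genotype may raise basal interferon signalling, though housing, sampling and litter were not recorded per library and stay open.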

How the results depend on the processing

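Fits without squamous libraries and of series DSS11 were chosen after the data were seen; the cause of a change was not tested, apart from settings that by construction fit fewer libraries or call fewer genes. Of the 690 named genes called, DESeq2 gave an adjusted p for 682 and kept all of these. RLE scaling kept 687, upper-quartile scaling 683, no low-count filter 654, limma voom with quality weights 645, the Xist covariate 534 and the changed batch term 464. Of the calls compared, fits to the 2 groups alone kept 439 of 669, batch 1 and batch 2 DSS libraries alone 308 of 390 and 3 of 111, the library series term 50 of 68, and fits without squamous libraries or of series DSS11 250 of 287 and 250 of 286; with each library left out in turn 6274 of 7393 calls were kept. Of the 116 gene lists passed, camera kept 112 with a preset and 5 with an estimated correlation, and a changed batch term kept 85. Fry on these fits moves slightly with the order of the groups in the design, tested after the data were seen: 116 and 114 lists were kept in 2 other orders (lost: endoplasmic reticulum stress genes in control cells and smooth muscle genes at day 3, adjusted p = 0.0550 and 0.0502), and tuft cell and apoptosis genes in control cells, goblet cell genes at day 3 and immediate early genes in day 8 tissue passed in another order alone (adjusted p = 0.0433, 0.0433, 0.0441 and 0.0486). A block by replicate number, whose pairing of the libraries is uncertain, kept 578 genes and 110 lists. The type I interferon list had an adjusted p = 0.168 with this block in day 0 tissue and 0.0531 for day in Tg tissue. No setting varied depth, which limits genes with no counts in a group to bounds.

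Counts of called genes moved by over 1.5 times as follows. With DESeq2 they were 167 (14 in the edgeR fit) for Tg against WT in control epithelial cells, 345 (0) for the epithelial interaction, 130 (1) and 2704 (998) for Tg against WT in tissue at day 0 and day 8, 2089 (943) for day in WT tissue and 537 (0) for the tissue interaction. With limma voom quality weights they were 3460 in control cells, 3093 (2052) for Tg against WT cells at day 3, 5587 (2626) for DSS in WT cells, 3510 for the epithelial interaction, 342 and 7272 for tissue at day 0 and day 8, 5977 for day in WT tissue and 6149 for the tissue interaction. With no low-count filter they were 69 in control cells, 2 for the epithelial interaction and 633 for day 8 tissue. Removing the batch term gave 9 in control cells, 984 at day 3, 1750 for DSS in WT cells and 505 in day 8 tissue, and adding it gave 3328 for day in Tg tissue (6585). The block gave 167, 3, 4 and 379 for control cells, the epithelial interaction, day 8 tissue and day in WT tissue. The Xist covariate gave 2 in control cells and 76 at day 3. Fits to the 2 groups alone gave 34 in control cells, 3 at day 3, 5255 for DSS in Tg cells (8182), 0 and 0 in tissue at day 0 and day 8, and 233 for day in WT tissue. Within batch 1 and batch 2 day 3 gave 691 and 30. Calls also changed by 1 or more on the log2 scale numbered 506 at day 3, and 901 and 2954 for DSS in WT and Tg cells. The library series term gave 90 for the tissue interaction. Without squamous libraries tissue gave 3 at day 0, 3679 at day 8, 538 for day in WT and 1562 for the interaction, and 2 at day 0 when WT day 0 library 1 was left out as well. Series DSS11 alone gave 3851, 620 and 1984 for day 8, day in WT and the interaction. Its genotype difference at day 8 rests on the same day 8 libraries as the fit without squamous libraries.

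Leaving out 1 library in turn gave 3 to 443 in control cells, 289 to 3276 at day 3, 1532 to 2393 for DSS in WT cells, 6730 to 8539 for DSS in Tg cells, 0 to 361 for the epithelial interaction, 1 each time in day 0 tissue, 132 to 3825 in day 8 tissue, 394 to 1129 and 5337 to 6503 for day in WT and Tg tissue, and 0 to 1776 for the tissue interaction. Directions reversed for Scd3 in day 8 tissue (-0.51 with voom quality weights, -1.53 without squamous libraries and -1.53 in series DSS11), Hbb-bt and Hbb-bs for day in WT tissue (-0.43 and -0.0054 with voom quality weights), Mmp7 and Mcm3 for day in Tg tissue (-1.50 and -0.068 with a batch term), and the interferon type I list for day in Tg tissue (adjusted p = 0.733 with a batch term).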

Other observations

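The tests of overlap, the tests of splits for both genotype comparisons and for DSS in WT among epithelial cells, and the fit without squamous libraries were chosen after the results were seen.

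WT and Tg epithelial cells responded to DSS in the same direction, in comparisons of groups with no library in common. Both used a shared batch term estimated from the DSS libraries of both genotypes, so their errors are not independent. 1015 genes rose and 1234 fell in both, against 264 and 310 if the calls were independent, and 0 genes were called in opposite directions. Across 18737 genes, which are not independent replicates, the changes had a Pearson correlation of 0.764. In tissue 634 genes rose and 224 fell from day 0 to day 8 in both genotypes, against 132 and 36.8 by independence, again with 0 in opposite directions. The day fits carry no batch term and day nearly coincides with batch, so a batch effect in both genotypes would give this agreement too.

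The genotype differences in epithelial cells at day 3 and in tissue at day 8 had few genes in common in the same direction. Of 17099 genes tested in both, 118 were higher in Tg epithelial cells and lower in Tg tissue, against 47 by independence. 16 were higher in both (12.3 by independence), 38 lower in both (43.3) and 4 lower then higher (11.3). Across genes the Pearson correlation was 0.0529. Reg3b was higher in Tg epithelial cells (10.98 ± 1.65) and lower in Tg tissue at day 8 (-10.36 ± 2.39, adjusted p = 0.0252, not called without WT day 8 library 3 or Tg day 8 library 3). Retnlb changed by 4.26 ± 0.88 and -7.32 ± 1.58 (not called in tissue without Tg day 8 library 3). The comparisons differ in material, day and mice, and the labels do not give the gut region of the epithelial cells, so the change over time was not tested.

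WT day 0 tissue library 3 had no counts of Xist or of Ddx3y, while each of the other 21 tissue libraries had 1 CPM or more of just 1 of them. In tissue, Ddx3y was counted in the day 0 libraries of series DSSIEC12 and not in those of series DSSIEC2. At day 8 it was counted in 3 of 4 libraries of series DSS10 and in none of series DSS11, so series and sex markers overlap.

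For each count of called genes, other splits of the same libraries were tried, the real split included. In Tg against WT epithelial cells at day 3, 2 of 100 splits called as many as the real 2052, the highest other calling 3851. That split does not follow the batches. It keeps the genotypes except that WT DSS library 2 and Tg DSS library 5 change places, which points to a structure of the samples beyond genotype. Casp3 was at 41.05 CPM in WT DSS library 2, where its group spanned 38.8 to 52.9 CPM, and at 11.4 CPM in Tg DSS library 5, the highest of a group that began at 8.32 CPM. Within batch 1 the count was 691. For DSS in WT epithelial cells 1 of 100 splits reached the real 2626 (highest other 2). For DSS in Tg cells 1 of 100 reached 8182 (highest other 4360, a split in which Tg DSS libraries 4 and 5 side with the controls). For day in WT tissue it was 1 of 100 (real 943, highest other 363) and for day in Tg tissue 1 of 100 (real 6585, highest other 1889). Among the splits tried only the real one reached each of these counts, so a random division of single libraries does not account for them. The splits ignored batch and library series. In tissue no series held both days, so a chance difference between series is not excluded there. For the comparison at day 3 the share of splits was low, but the splits ignored batch and another split called 3851 genes. A chance alignment of genotype with that structure is therefore not excluded. For tissue at day 0 it was 1 of 100 (real 1, highest other 0), but the self-test made 1 false call there, so a count of 1 gene decides nothing.

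Chance was also not excluded in control epithelial cells, nor in tissue at day 8 over all libraries. In control epithelial cells 2 of 35 splits called as many as the real 14, and exchanging WT control library 1 with Tg control library 2 called 148, which points to a structure of the samples. In tissue at day 8, 7 of 100 splits called as many as the real 998, and placing WT day 8 library 2, a squamous library, with the 5 Tg libraries called 4433, so the squamous libraries form a structure of the samples. Without the squamous libraries 1 of the 56 splits, the real one, called 3679 (highest other 2958). The real split ranked first there, but this subset was chosen after the data were seen, so chance is not excluded by it. In the interactions the real count was 0, which all 100 of 100 splits must reach, so the splits say nothing on chance there. The highest other split called 1137 genes in epithelial cells and 1044 in tissue. These splits exchanged genotype labels within each treatment or day and ignored batch. In that epithelial split every DSS library changed its label except WT DSS library 2 and Tg DSS library 5. Apart from the sign, this is the same exchange at DSS as in the split that called 3851 genes at day 3. A structure of the samples beyond genotype can therefore enter the interaction too.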
